A study of Homo sapiens with 24 samples.

How the data were processed

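Chromatin immunoprecipitation with sequencing was done by the authors on RWPE1 cells fixed in 0.3% formaldehyde for 30 min and quenched with 125 mM glycine, per the labels' protocols. SWI/SNF subunits were precipitated from MNase-cut chromatin of SCHLAP1 cells, per the series' design text. The labels put the 24 samples into 12 groups of 2. Bowtie2, SAMtools, MACS2 and deepTools 2.5.2 and the build hg38 are named in the submitters' processing notes, without their roles. Whether the replicates were pooled for peak calling, the threshold, the input used and the filter are not given in the sources used here.

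The deposited peak lists, 1 each for BRG1, BRM and SNF5, give for every peak its start and end in hg38 (counted from 1), its width in bp, its place (promoter, intron, exon or distal), the nearest TSS and the distance to it, per the file headers. They hold no score, enrichment, p-value or count of reads. Peaks are numbered, and 90, 74 and 49 numbers are absent from the BRG1, BRM and SNF5 lists. Promoter peaks lay at most 998 bp from the TSS and all others at least 999 bp. The distances fit counting from the middle of a peak, so a wide peak that covers a TSS can be annotated as not promoter. The BRG1 peak of CCND1 (69640091 to 69644744) covered the start of the gene (69641156). It was annotated as intron, 1184 bp from the TSS. The narrowest peaks were 331, 310 and 151 bp. A peak caller's minimum width and the depth of a library both move the number and width of peaks, so counts and widths are not compared as amounts of protein.

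Gene names were matched to RefSeq genes of GRCh38.p14 on the same chromosome by symbol or by a synonym of 1 gene only, which matched 81.4% of BRG1, 86.9% of BRM and 90.5% of SNF5 peaks. No genome sequence was used here, so a planned search for transcription factor motifs was not run. Designs, gene lists, the rule for named genes and most alternatives were set before the data were examined. The planned analysis used the authors' enrichment to rank peaks and to compare shared with unshared sites. The lists hold none, so peak width was used in its place, in the choice of named genes too.

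Overlaps were counted with bedtools 2.31.1 at a minimum of 1 bp, with exact (Clopper-Pearson) binomial intervals at 95% confidence. These treat peaks as trials, which they are not strictly, since neighbouring peaks depend on each other, and they cover counting error only. Each share was set against 1000 circular shifts of the other list along the span of each chromosome (100 for alternatives). Differences of promoter shares have intervals from 10000 bootstrap draws of the 24 chromosomes, and ratios of median widths from 2000 draws. Each gene list was placed among 10000 random lists of protein-coding genes matched on gene length in 10 bins, and called above or below beyond the 97.5th or under the 2.5th percentile. This describes the lists and gives no p-value, since genes are not replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

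Named were, for each gene list, up to 4 members with the widest BRG1 peak and up to 2 members with no named peak, first by alphabet; the 10 sites in all 3 lists with the lowest sum of width ranks; the 5 widest peaks in 1 list only for each subunit; the 5 genes with the most BRG1 peaks; and SCHLAP1, its neighbours and the genes of the 3 subunits. The 19 lists were those in the report's account of genes and the genes of the SCHLAP1 locus, 413 entries in all, of which 7 genes stand on more than 1 list. Some members that this rule takes are not reported here. A member counts as named when a peak gives it as nearest TSS, so a peak given for a gene can lie outside it.

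The routines were tested on simulated data. Of 4959 simulated peaks with 40.3% placed on BRG1 peaks, 40.3% were found to overlap. For 4000 randomly placed peaks the overlap of 2.40% lay within the shifts (1.60 to 2.70%). Over 200 simulated pairs of lists the bootstrap interval held the true difference in 96.5%. These simulated peaks were independent, with the same share on every chromosome and chromosomes equally likely. The coverage was therefore not tested for dependent neighbours, unequal chromosomes or shares that differ between chromosomes, as in the real lists. Of 360 gene lists tested on genes bound at random, 3.33% were called, and of 90 lists made richer in bound genes 98.9% were called above.

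The alternatives were other rules of overlap, other distances for promoters, narrower or wider peaks, equal numbers of peaks, other sets of chromosomes, promoter peaks only and unmatched random lists. Samples of the histone marks and inputs were not analysed here.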

Results

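The series asked whether SWI/SNF stays on chromatin when SCHLAP1 is made, and profiled where the SWI/SNF chromatin remodelling complex lies in prostate epithelial cells that make SCHLAP1, a long noncoding RNA studied in prostate cancer. RWPE1, an established line of benign human prostate epithelial cells, carried either SCHLAP1 or the control gene LACZ from a lentivirus and was kept under 2.5 ug/mL blasticidin. The 24 samples form 12 groups of 2. BRG1, BRM, SNF5 and their input were profiled on MNase-cut chromatin of SCHLAP1 cells, and H3K27ac, H3K4me1, H3K4me3 and their input on sonicated chromatin of both cell types. BRG1 and BRM are the alternative ATPases of the complex, and SNF5 is a core subunit. The peak lists of BRG1, BRM and SNF5 in SCHLAP1 cells, 1 list for each subunit, were analysed here. The histone marks and the inputs, and with them the comparison of SCHLAP1 with LACZ cells, were not analysed here. No subunit was profiled in LACZ cells, so these lists cannot show an effect of SCHLAP1 on where SWI/SNF lies. The lists hold positions without read counts, so the depth behind each list is unknown. No value has a replicate spread, and a site missing from a list is a site without a called peak, not one shown to lack the protein.

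BRG1 had the most peaks. By the deposited annotation, which takes promoters as within 1000 bp, BRM and SNF5 peaks lay mostly at promoters, while most BRG1 peaks did not. The lists held 51504 BRG1, 22157 BRM and 6489 SNF5 peaks, covering 44.8, 15.3 and 1.65 Mb. Promoters, within 1000 bp of a transcription start site (TSS), held 37.3% of BRG1 peaks (95% exact binomial interval 36.9 to 37.7), 62.8% of BRM peaks (62.2 to 63.4) and 81.3% of SNF5 peaks (80.3 to 82.2). Introns held 37.7% of BRG1, 19.6% of BRM and 7.98% of SNF5 peaks, and distal intergenic sequence held 21.9%, 14.3% and 8.43%. Exons held 3.11% of BRG1 (2.96 to 3.26), 3.37% of BRM (3.14 to 3.62) and 2.31% of SNF5 peaks (1.96 to 2.71). The median distance to the nearest TSS was 2771 bp for BRG1, 383 bp for BRM and 159 bp for SNF5. Distances fit counting from the middle of a peak, so wide peaks that cover a TSS can be annotated as not promoter. With the limit at 3 kb, 51.1% of BRG1 peaks lay near a TSS (50.7 to 51.5). Of 19974 protein-coding genes, 63.7% were named as nearest TSS by a BRG1 peak, 49.7% by a BRM peak and 19.7% by an SNF5 peak.

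**Figure D1:**
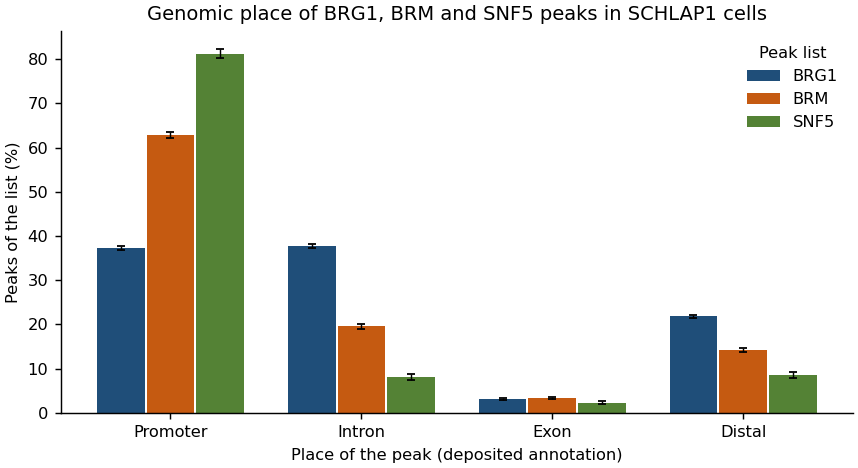
Share of the peaks of each list (y axis, percent) by the place the deposited annotation gives them (x axis), for BRG1, BRM and SNF5 in SCHLAP1 cells, with 95% exact binomial intervals over peaks. Promoter peaks rise from 37.3% for BRG1 to 62.8% for BRM and 81.3% for SNF5, while intron peaks fall from 37.7% to 19.6% and 7.98%.

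With whole chromosomes resampled, the promoter share of BRM exceeded that of BRG1 by 25.5 percentage points (95% bootstrap interval 22.7 to 28.3). That of SNF5 exceeded BRG1 by 44.0 points (39.9 to 47.6) and BRM by 18.5 points (16.1 to 20.7). The intervals cover variation between chromosomes, not between replicates. BRG1 peaks were wider (median 667 bp, against 547 bp for BRM and 212 bp for SNF5). Wide peaks can lose the promoter label while they cover a TSS, and how much of the differences comes from this was not tested. Among the 6489 widest peaks of each list the excess of BRM over BRG1 was 13.7 points, that of SNF5 over BRG1 15.9 points and over BRM 2.20 points, so the differences moved with the number and width of the peaks taken.

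The shorter lists lay largely within the BRG1 list: nearly all SNF5 peaks and most BRM peaks fell on BRG1 peaks, while most BRG1 peaks met neither other list. BRG1 peaks met 96.1% of SNF5 peaks (95.6 to 96.5) and 92.2% of BRM peaks (91.8 to 92.5), with at least 1 bp of overlap. BRM peaks met 91.9% of SNF5 peaks (91.2 to 92.6). In the other direction, 35.7% of BRG1 peaks met a BRM peak and 9.58% met an SNF5 peak, and 21.9% of BRM peaks met an SNF5 peak. When the other list was shifted along each chromosome 1000 times, BRG1 peaks met on average 2.46% of SNF5 peaks (at most 3.51%) and 3.19% of BRM peaks, and none of the 6 shares was reached by any shift. The shifts do not keep peaks at promoters, so lists rich in promoters can exceed them without sharing particular sites. No background matched on promoters was run. Of peaks not annotated as promoter, 85.9% of the 1215 SNF5 peaks and 87.7% of the 8241 BRM peaks met a BRG1 peak. No shifts were run for these peaks alone, and some of them may lie near or cover a TSS. SNF5 peaks were narrow (median 212 bp, against 547 bp for BRM and 667 bp for BRG1), so that a demand for reciprocal overlap of 50% left 2.13% of SNF5 peaks on BRG1 peaks. Among the 6489 widest peaks of each list, 57.6% of SNF5 peaks met a BRG1 peak.

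The shared site with the lowest sum of width ranks over the 3 lists was MYC, which encodes a transcription factor that drives cell growth. Its BRG1 peak ran over 6691 bp of chromosome 8 (127733750 to 127740440, hg38), and held a BRM peak of 5062 bp and 4 SNF5 peaks, the widest of 1103 bp. Of the other sites among the first 10 by this sum, one lay at LAMA5, a laminin chain of the basement membrane, with a BRG1 peak of 6578 bp in an intron (chromosome 20, 62360662 to 62367239) and 6 SNF5 peaks inside it. At NDRG1 a promoter peak of 4704 bp on chromosome 8 (133294072 to 133298775) held 3 SNF5 peaks. KMT2E, which encodes a protein of the histone methyltransferase family, had a promoter peak of 5605 bp on chromosome 7 (105011816 to 105017420). ZFAS1, a noncoding RNA gene, had one of 8366 bp on chromosome 20 (49275288 to 49283653). The remaining sites were named for MIR3193, AC010997.3, TNRC18, DNAJB12 and AL021578.1, the last with a BRG1 peak of 13194 bp (chromosome 20, 45336230 to 45349423) that held 8 SNF5 peaks. MIR3193, LAMA5, ZFAS1 and AL021578.1 lie on chromosome 20, where SNF5 met 31.8% of BRG1 promoter peaks, against 21.2% over all chromosomes. The other sites lie on chromosomes 7 (19.6%), 8 (21.7%) and 10 (30.0%). The ranks were not adjusted for differences between chromosomes. Genes with the most BRG1 peaks were ZMIZ1 with 38, of which 1 lay at a promoter, ARHGAP26 with 33, DAB2IP and EFNA5 with 32 each, and EGFR, the epidermal growth factor receptor, with 31. The same genes had 25, 9, 13, 9 and 12 BRM peaks and 5, 1, 4, 4 and 1 SNF5 peaks. They are long, from 192612 bp (EGFR) to 458635 bp (ARHGAP26), and the counts were not adjusted for gene length.

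**Figure D2:**
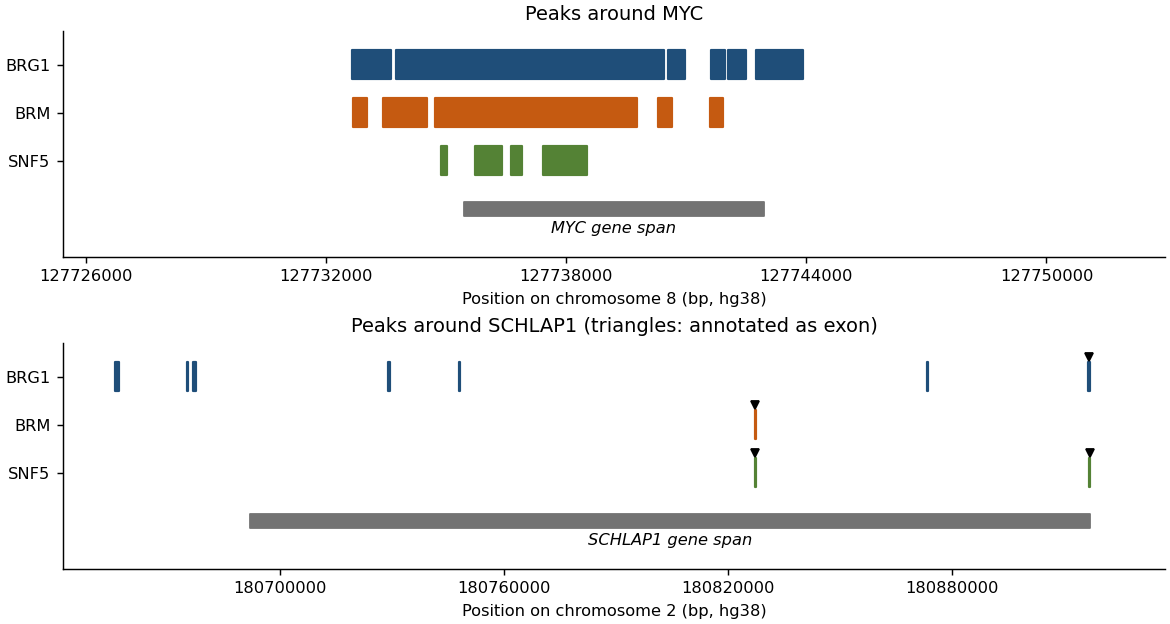
Peaks of the 3 lists (rows of bars) along chromosome 8 around MYC and along chromosome 2 around SCHLAP1 (x axis, position in bp, hg38), with the gene span in grey; peaks narrower than the line are drawn as thin lines. At MYC the 6691 bp BRG1 peak covers 4 SNF5 peaks; at SCHLAP1 triangles mark the peaks annotated as exon, in the BRG1, BRM and SNF5 lists.

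BRG1 sites that all 3 lists shared were wide promoter sites, and sites of BRG1 alone were narrower and mostly away from promoters. Of BRG1 peaks, 4749 (9.22%) met both other lists, 13621 (26.4%) BRM only, 185 SNF5 only and 32949 (64.0%) neither. Promoters held 83.6% of the shared peaks (82.6 to 84.7) and 22.1% of the BRG1-only peaks (21.6 to 22.5), a difference of 61.6 points (bootstrap interval 58.1 to 64.6). The median width was 1606 bp for shared and 510 bp for BRG1-only peaks, a ratio of 3.15 (2.98 to 3.29), and the ratio was 3.20 at promoters and 3.08 elsewhere. With BRG1 peaks in 10 bins of equal size by width, the share that met SNF5 rose from 0.621% in the narrowest bin to 43.9% in the widest, and the share that met BRM from 6.72% to 91.7%. In the widest bin, shifted lists of SNF5 met 0.626% and those of BRM 2.43% of peaks on average. There, 97.6% of promoter and 79.7% of other BRG1 peaks met BRM, and 55.2% and 21.2% met SNF5. Peak width stood in for the enrichment, of which the lists hold no column, and the ratio fell to 1.26 among BRG1 peaks narrower than the median.

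**Figure D3:**
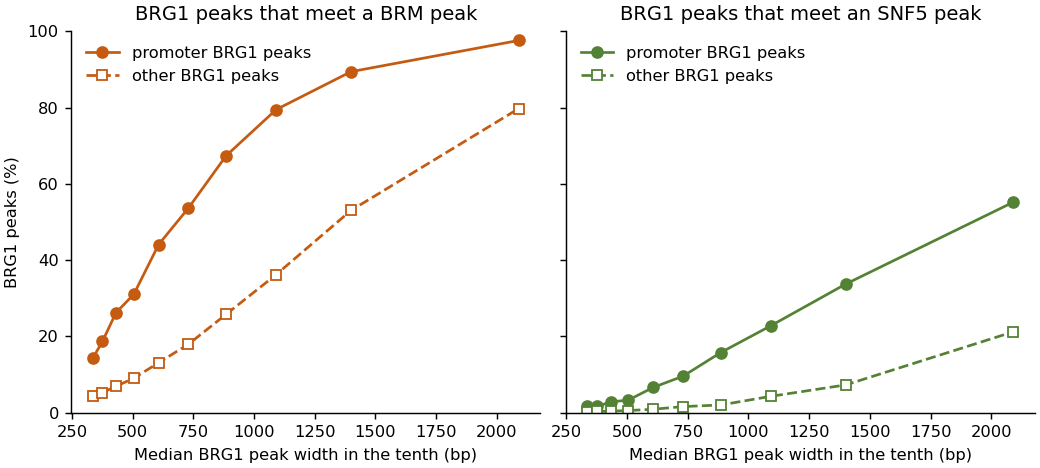
BRG1 peaks that meet a BRM peak (left) or an SNF5 peak (right), in percent (y axis), against the median width in bp of each of 10 bins of BRG1 peaks by width (x axis), for promoter peaks (filled) and other peaks (open). Both shares rise with width, to 97.6% and 79.7% for BRM and 55.2% and 21.2% for SNF5 in the widest bin, and lie higher at promoters in every bin.

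The widest BRG1 peak that met neither other list lay at the promoter of COL17A1, a collagen of the attachment of basal epithelial cells to the basement membrane (chromosome 10, 104082795 to 104086965, 4171 bp). PID1 (3498 bp, intron), MIER1 (3370 bp, promoter), MED12L (3323 bp, promoter) and MIR31HG (3237 bp, distal) followed. A BRM peak named for COL17A1 (104082072 to 104082510) ended shortly before the COL17A1 BRG1 peak. Within 1 kb, 44.3% of all BRG1 peaks met a BRM peak. BRM had 1691 peaks in no other list, the widest being named for AC026495.1 (1318 bp, distal), LHX3 (1054 bp, intron), BHLHE40 (985 bp, promoter), C11orf96 (946 bp, exon) and PPFIA3 (926 bp, promoter). SNF5 had 190, with widths of at most 358 bp, the widest named for LAMA5, LENG1, AL583722.1, LINC01606 and FP325313.1.

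Genes of basal epithelium, the layer that lies on the basement membrane, were named by peaks of all 3 subunits more often than random genes of matched length. The random genes of this and the other lists were not matched on expression or active promoters. BRG1 named 24 of 26 basal genes (92.3%; random mean 66.9%, upper end of the central 95% of random lists 84.6%). BRM named 23 (88.5%; 51.9%, 69.2%) and SNF5 15 (57.7%; 20.8%, 38.5%). ITGA3, an integrin of epithelial adhesion, had a BRG1 peak of 6050 bp (chromosome 17, 50054784 to 50060833), S100A2 one of 3656 bp, COL17A1 one of 4171 bp and EGFR one of 3543 bp. DSG3, a desmosomal cadherin, was named by no peak. Of 21 luminal prostate genes, 15, 12 and 3 were named, which lay within the random range for every subunit. Among these, NDRG1 (4704 bp), FKBP5 (3501 bp), KRT8 (2250 bp) and FOXA1 (2237 bp) had the widest BRG1 peaks. KLK2, a kallikrein protease gene, had no peak.

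Genes of the AP-1 transcription factors and of the YAP/TEAD programme were also rich in peaks. BRG1, BRM and SNF5 named 13, 12 and 10 of 15 AP-1 genes, above the random range for each subunit. The call for BRG1 ended with promoter peaks only and with unmatched random lists. The widest BRG1 peaks were named for ATF3 (3324 bp BRG1 peak), JUNB (2667 bp), MAFK (2222 bp) and FOSL2 (2134 bp). That of FOSL2 was distal, 14329 bp from the TSS. BATF and BATF2, members best known from immune cells, had none. Of 22 YAP/TEAD targets they named 21, 15 and 9, above the range for BRG1 and SNF5 and within it for BRM. With peaks within 1 kb of the gene span the call for SNF5 ended, and with the wider 50% of each list or the 6489 widest peaks BRM was above. NUAK2 (6366 bp), MYOF (5046 bp), F3 (4304 bp) and GADD45A (3582 bp) led. FOXF2 was named by no peak, although 2 BRG1 peaks and 1 BRM peak lay within 1 kb of it.

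Targets of p53, cell cycle genes and TGF-beta response genes were nearly all named by BRG1 and BRM. BRG1, BRM and SNF5 named 20, 19 and 9 of 20 p53 targets, 21, 20 and 10 of 21 cell cycle genes and 20, 20 and 10 of 20 TGF-beta response genes, all above the random range. With the wider 50% of each list the SNF5 calls of the p53 and cell cycle lists ended, and with peaks within 1 kb of the gene span that of the p53 list. GADD45A led the p53 targets with its BRG1 peak of 3582 bp. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, had a BRG1 peak of 3340 bp and 4 SNF5 peaks, BBC3 and BTG2 had BRG1 peaks of 2634 and 2471 bp, and no SNF5 peak was named for either. CCND1, the gene of cyclin D1, had a BRG1 peak of 4654 bp, MCM4 one of 2896 bp, CCNE2 one of 2238 bp and AURKA one of 1901 bp. SMAD3 had 22 BRG1 peaks and no SNF5 peak, PMEPA1 19 and 5, SKI 7 and 0, and SMAD6 4 and 1.

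Ribosomal protein genes had the highest SNF5 share of the 18 lists but for the AP-1 genes. SNF5 named 26 of 40 (65.0%; random 5.00 to 27.5), BRM 36 and BRG1 33. RPL8 had 3 peaks in every list, with a BRG1 peak of 3643 bp, and RPL12, RPS12 and RPL24 had BRG1 peaks of 3296, 3265 and 3093 bp. RPL14 and RPL32, on the part of chromosome 3 where SNF5 peaks were almost missing, had no peak. HOX genes, which set body pattern, were named by BRG1 in 25 and by BRM in 23 of 39 cases, above the range, and by SNF5 in 8, within it. Both HOX calls ended with unmatched random lists. HOXA9 (4245 bp), HOXD11 (3530 bp), HOXC11 (3439 bp) and HOXA10 (3409 bp) led, and HOXA11 was named by no peak although 2 BRG1 and 3 BRM peaks lay inside or within 1 kb of the gene. For the SWI/SNF subunit genes the counts were 28, 22 and 6 of 29, above the range for BRG1 and BRM and within it for SNF5. The BRM call ended in 4 of 6 alternatives, among them promoter peaks only, and the BRG1 call with the 6489 widest peaks. SS18L1 (2738 bp), SMARCD2 (2365 bp), ARID1B (2101 bp) and ACTB (2087 bp) led. SMARCE1 was named by no peak, with 1 peak of each list within 1 kb of the gene.

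Interferon and NF-kB response genes were named above the random range by BRG1 peaks, and within it by BRM and SNF5 peaks. Of 25 interferon response genes 21, 15 and 4 were named by BRG1, BRM and SNF5, and of 20 NF-kB response genes 17, 11 and 3. The difference between subunits was not tested, and the BRG1 call of the interferon list ended with the wider 50% of each list and with the 6489 widest peaks. With the 6489 widest peaks the NF-kB list was above the range for BRM as well. IRF1 (3422 bp) had 8 BRG1 and 5 SNF5 peaks, ISG15 (2625 bp), IFIH1 (2542 bp) and ISG20 (2474 bp) followed, and IFI27 and IFI6 had none. The ISG15 peak (999630 to 1002254) lay outside the RefSeq span of the gene, which starts at 1013497. NFKB2 (2978 bp) had 4 SNF5 peaks and NFKBIA (2654 bp) 1, TNFAIP2 (2590 bp) and TNFAIP3 (2337 bp) had no SNF5 peak, and CCL2 and RELB were named by no peak. Mesenchymal genes (17, 10 and 6 of 20) lay within the range for all subunits, though above it for BRG1 with unmatched random lists and with the wider 50% of each list. ITGA5 (2863 bp), VIM (2649 bp), TGFBI (2137 bp) and COL1A1 (2065 bp) led, and CDH2 and COL3A1 had no peak.

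Hepatocyte, blood cell and stromal genes had the lowest BRM shares of the 18 lists. Of 20 hepatocyte genes BRG1 named 5 (25%; random mean 60.2%), BRM 1 and SNF5 0, below the range for each. HNF4A (696 bp), F2 (654 bp), AHSG (567 bp) and CYP2E1 (441 bp) had narrow BRG1 peaks, and ALB and APOA1 were named by none. Of 20 blood cell genes 8, 2 and 0 were named, and of 16 stromal and endothelial genes 11, 4 and 0, below the range for BRM and SNF5 and within it for BRG1. The BRG1 share of the blood list was below the range in 5 of 6 alternatives, and that of the stromal list in 3, namely promoter peaks only, the 6489 widest peaks and peaks within 1 kb of the gene span. With the 6489 widest peaks the BRM calls of both ended, and with the wider 50% of each list the SNF5 calls of all 3 lists ended. CD8A (1010 bp), CD14 (929 bp), ITGAM (894 bp) and CD79A (489 bp, distal) led the blood list. COL6A3 (1256 bp), TEK (1063 bp), PDGFRB (1061 bp) and CDH5 (935 bp) led the stromal list, where the COL6A3 peak was distal, 31359 bp from the TSS. CD2, ACTA2 and DCN were named by no peak. The counts were 11, 9 and 1 of 20 neuronal genes, with GAD1 (2575 bp), GRIN1 (2210 bp), CAMK2A (2127 bp) and SYT1 (1147 bp) ahead and DCX and ELAVL4 without a peak. The GRIN1 and CAMK2A peaks were distal, 8547 and 5525 bp from the TSS. Of 10 neuroendocrine genes 7, 4 and 0 were named, with CHGA (896 bp), ENO2 (839 bp), SCG3 (651 bp) and CHGB (586 bp) ahead and INSM1 without a named peak. Both lists lay within the range for every subunit, but neuronal genes were below it for all 3 with promoter peaks only and with peaks within 1 kb of the gene span.

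Of the 18 lists, 11 lay above and 1 below the random range for BRG1, 8 and 3 for BRM and 7 and 3 for SNF5. The count below for BRG1 was 4 when only promoter peaks were used, and no list went from above to below in any alternative. A peak names 1 TSS alone, so a gene can be missed where a neighbour lies nearer, and the genes of a list are not independent replicates. Matching was on length alone, so a list above the range is not shown to be a particular target. Of 77 mitochondrial ribosomal protein genes, 96.1% had a BRG1 peak within 1 kb of their span, against 70.3% of all coding genes.

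**Figure D4:**
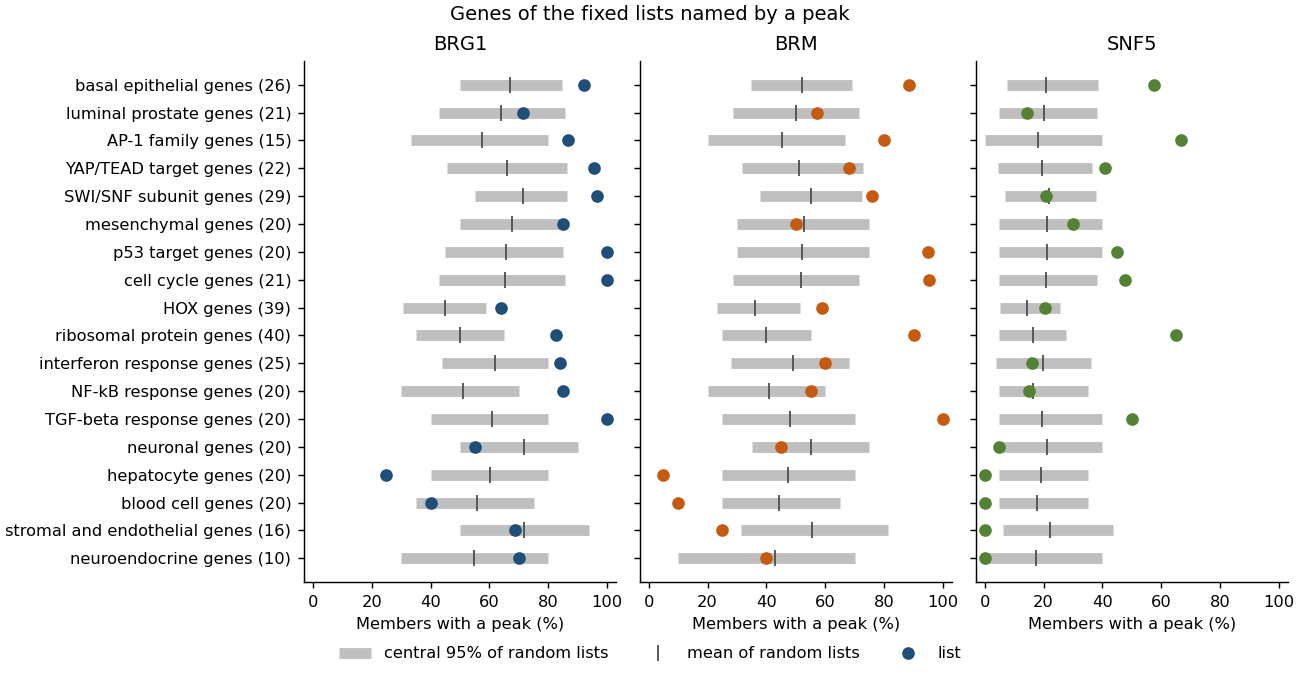
Share of the members of each of the 18 gene lists (number of members in parentheses) named by a BRG1, BRM or SNF5 peak (x axis, percent; dots), with the mean (tick) and central 95% (grey bar) of 10000 random gene lists matched on gene length. Basal epithelial genes stand at 92.3%, 88.5% and 57.7%, to the right of the grey bar for every subunit, and hepatocyte genes at 25%, 5.00% and 0%, to its left.

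Peaks at the SCHLAP1 locus were few and narrow. BRG1 had 5 peaks named for it, of 331 to 503 bp, all annotated as intron and outside the RefSeq span of the gene (chromosome 2, 180692104 to 180916939), and none met another list. Inside the span lay 4 BRG1, 1 BRM and 2 SNF5 peaks. Those annotated as exon were an SNF5 peak at 180827235 to 180827457 within a BRM peak at 180827186 to 180827599, and an SNF5 peak at 180916784 to 180916934 that met a BRG1 peak at 180916539 to 180916869. The last SNF5 peak ended 5 bp before the end of the gene. The annotation does not name the gene of the exon, and the TSS nearest to these SNF5 peaks lay 26117 and 22436 bp away. Nearby, UBE2E3 was named by 2 BRG1 peaks and CWC22 by 3 BRG1 peaks and 1 BRM peak. Elsewhere in the locus SSFA2 (1778 bp), PPP1R1C (611 bp) and CERKL (592 bp) had BRG1 promoter peaks, and NEUROD1 and PDE1A were named by no peak. SMARCA4, which encodes BRG1, was named by 4 BRG1 and 2 BRM peaks, SMARCA2, which encodes BRM, by 4 and 1, and SMARCB1, which encodes SNF5, by 1 and 1. SNF5 peaks were named for none of these genes.

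Chromosomes 22 and X held almost no SNF5 peaks and few BRG1 and BRM peaks. SNF5 had 2 peaks on chromosome 22 and 0 on X. BRG1 had 0.377 promoter peaks per protein-coding gene on 22 and 0.323 on X. With Y left out, which had no BRG1 peak, the next lowest was chromosome 18 with 0.767 and the highest chromosome 15 with 1.21. An SNF5 peak met 0.225% of the 444 BRG1 promoter peaks on 22 and X (0.00570 to 1.25) and 21.7% of the 18767 elsewhere (21.1 to 22.3). Chromosome 3 before 90 Mb, chromosome 8 before 40 Mb and chromosome 18 after 30 Mb, chosen after SNF5 peaks were seen to be missing there, held 3 SNF5 peaks against 458 on the rest of the same chromosomes. Windows of 10 Mb were kept, 285 in all, where they held at least 10 protein-coding genes and at least 10 BRG1 promoter peaks. Windows with the fewest BRG1 promoter peaks were thus left out. Of the 256 kept windows outside 22, X and these parts, 16 had a low SNF5 share of BRG1 promoter peaks. The exact interval of that share lay below the 22.2% over all 256, where counting error alone would give 4.13 windows. Of the 16, 6 also had few BRG1 promoter peaks per gene (0.296 to 0.674). They lay on chromosome 4 before 10 Mb (2.50% with SNF5), chromosome 9 before 10 Mb (0%) and chromosome 7 from 120 to 160 Mb (6.06%, 0%, 3.85% and 0%). BRM met 15% to 45.5% of the BRG1 promoter peaks in these 6 windows. The other 10, on chromosomes 1, 2, 4, 11, 14, 15 and 17, had SNF5 shares of 8.33% to 14.6% with 0.915 to 2.46 BRG1 promoter peaks per gene, and BRM met 51.9% to 69.9% of these peaks. Across all 285 windows, BRG1 promoter peaks per gene rose with the share of them that met SNF5 (Pearson r 0.407, Spearman rho 0.293; r 0.440 without the 2 windows farthest from the median). The permutation p was 1e-05 for each, the smallest that 100000 permutations can give, and 2e-05 for rho after Benjamini-Hochberg adjustment over 6 relations. Over the 256 windows r was 0.0665 (permutation p 0.288) and rho 0.0382 (permutation p 0.543, adjusted 0.652). The parts left out were chosen by their lack of SNF5 peaks, so neither value is independent of that choice. The windows are not independent, as neighbours had like SNF5 shares (rho 0.462). DSG3, RPL14 and RPL32 lie in the parts of chromosomes 3 and 18, DCX on X and SMARCB1 on 22.

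**Figure D5:**
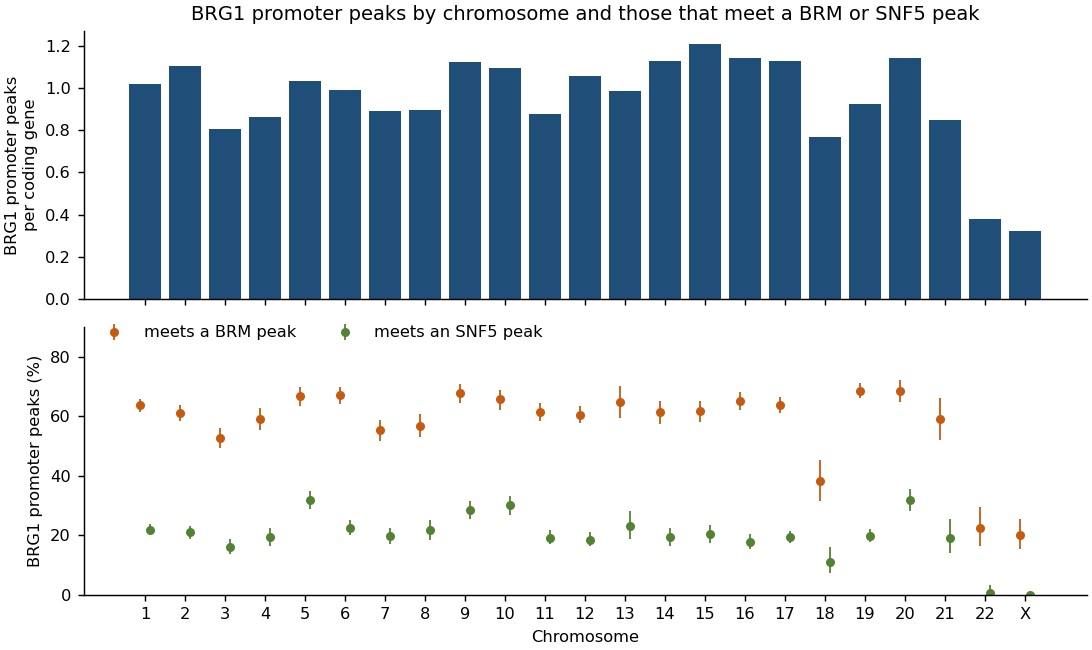
BRG1 promoter peaks per protein-coding gene by chromosome (top, bars) and the share of these peaks that meet a BRM or SNF5 peak (bottom, percent, with 95% exact binomial intervals); Y, which has no BRG1 peak, is not drawn. Chromosomes 22 and X stand lowest in both, at 0.377 and 0.323 peaks per gene and at 0.588% and 0% with an SNF5 peak.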

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

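The alternatives with the wider 50% or the widest peaks, by gene span and without chromosomes 22 and X and parts of 3, 8 and 18 were chosen after the data were seen, as was the ratio of widths at promoters, elsewhere and by reciprocal overlap. All 48 alternatives for the 6 overlap shares stayed above the shifted lists, though the shares moved far: under reciprocal overlap of 50%, 2.13% of SNF5 peaks met BRG1 and 8.45% met BRM, as narrow SNF5 peaks cannot cover 50% of most wide ones, while within 1 kb 97.7% and 95.5% did. With the 6489 widest peaks of each list, 57.6% of SNF5 peaks met BRG1 and 58.7% of BRG1 peaks met BRM. Shifted lists do not keep peaks at promoters, so lists rich in promoters can stay above them by that alone. All 21 alternatives for the 4 promoter share differences kept an interval above 0; SNF5 exceeded BRM by 2.20 (with the widest peaks, lower bound 0.0318) to 26.1 points and BRG1 by 15.9 to 50.3. Of 18 alternatives for the 3 promoter shares themselves, 15 moved out of the main interval, and within 3 kb of a TSS the BRG1 share was 51.1%. The ratio of widths stayed above 1 in 5 alternatives (1.26 to 3.20). The numbers of lists above the random range stayed within 1.5 times. The lists below it for BRG1 were 4 with promoter peaks only, 2 with unmatched random lists, 2 with the wider 50% of each list, 3 with the widest peaks in equal number and 4 with peaks within 1 kb of the gene span, against 1. For BRM they were 1 with the widest peaks in equal number, against 3, and for SNF5 0 with the wider 50%, against 3. In that SNF5 alternative the hepatocyte, blood cell and stromal lists, each with 0 named members, stood at percentiles of 5.08 to 5.67. So few random genes were named there that 0 was not below the range. The other causes were not tested. No list went from above to below. The alternative without regions of few SNF5 peaks keeps 16 windows of low SNF5 share on other chromosomes. Merging touching peaks moved nothing, and leaving out Y removed 1 SNF5 peak. Ranking by the authors' score, other score columns and motif windows were not run, since the lists hold no score and no genome was used. No paired analysis was possible because each subunit has 1 list, with no values for its replicates; for the same reason no replicate could be left out. Depth is unknown, so absent peaks set no limit on occupancy.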

Other observations

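All tests in this part were chosen after the data were seen, except the comparison of promoter with other BRG1 peaks in the parts of chromosomes 3, 8 and 18, whose outcome was stated before it was computed, though the promoter shares of 22 and X had been seen. The rule for the relation over windows was reworded before its last value (rho 0.0382) was computed, and under the earlier wording that value would have counted against fewer reads per site. Transfer RNA genes, which RNA polymerase III transcribes, were met by peaks of all 3 lists: 242 of 443 by BRG1 (54.6%; 95% exact interval 49.9 to 59.3), 201 by BRM (45.4%) and 154 by SNF5 (34.8%; 30.3 to 39.4). Shifted lists met at most 7.22%, 3.61% and 0.903%. Of the 154 genes with an SNF5 peak, 152 also met a BRG1 peak and 141 a BRM peak. Reads of near-identical copies are hard to place, and among the 202 genes whose symbol marks no second copy the shares were 49.5%, 37.1% and 32.2%. Outside promoters, 91 of 1215 SNF5 peaks (7.49%), 100 of 8241 BRM peaks (1.21%) and 129 of 32293 BRG1 peaks (0.399%) lay on a transfer RNA gene. By count BRG1 had the most, so these shares depend on the length of the lists.

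Peaks within 1 kb of gene spans differed between gene families. These shares were not matched on gene length, and a longer span has more room to meet a peak. Olfactory receptor genes (392) met BRG1 in 1.53% and SNF5 in 0.765%, and keratin-associated protein genes (94) in 3.19% and 0%, against 70.3% and 24.3% of all 19974 coding genes. BRG1 met 96.1% of 77 mitochondrial ribosomal protein genes (89.0 to 99.2), 92.0% of 50 proteasome genes and 94.6% of 37 NADH dehydrogenase subunit genes. The SNF5 shares of these families, at 33.8% (23.4 to 45.4), 30.0% (17.9 to 44.6) and 37.8% (22.5 to 55.2), have intervals that hold the share of all coding genes. Collagen genes (44) met BRG1 in 79.5% and SNF5 in 9.09% (2.53 to 21.7). Histone genes (70.9% and 27.8%) and ZNF genes (73.1% and 23.4%) lay near the shares of all coding genes. Among the HOX clusters, BRG1 peaks covered 42.6% of HOXA, 16.6% of HOXC, 16.5% of HOXD and 3.37% of HOXB. SNF5 had 9 peaks in HOXA, 5 in HOXD, 2 in HOXB and 0 in HOXC.

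SNF5 peaks were almost missing from chromosomes 22 and X and parts of 3, 8 and 18 and were few in 6 windows of 4, 7 and 9 (0% to 6.06% of BRG1 promoter peaks). Removal by the filter is argued against on 22 and X, since at most 24 peak numbers are absent next to them, where 92.5 peaks would match the BRG1 list (lower Poisson limit 74), and fewer promoters are argued against, since 0.225% of BRG1 promoter peaks there met an SNF5 peak. Fewer reads per site, as a lower DNA copy number would give, could lower all 3 lists, and in the parts 25.4% of BRG1 promoter peaks met BRM, against 62.7% on the rest of these chromosomes, while the 6 windows had 0.296 to 0.674 BRG1 promoter peaks per gene and 10 others with milder SNF5 shares (8.33% to 14.6%) had 0.915 to 2.46 (counting error alone would give 4.13 low windows of 256). The relation over windows does not decide, since with the regions it restates what prompted it (rho 0.293) and without them it leaves out the lowest SNF5 shares by choice (rho 0.0382, permutation p 0.543). Fewer reads and closed chromatin, the biological explanation left untested, cannot be told apart, since inputs and marks were not analysed here.

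BRM and SNF5 lists were richer in promoters than the BRG1 list. For list length alone, with the widest peaks kept, promoters held 65.3% of the 6489 widest BRG1 peaks (64.2 to 66.5). They held 79.1% of as many of the widest BRM peaks (78.1 to 80.1) and 81.3% of as many SNF5 peaks. These shares do not decide on list length, since width is not strength. The widest BRG1 peaks can also be annotated as not promoter while they cover a TSS. That the shorter lists hold only the strongest sites may account for part of the pattern. In the parts of chromosomes 3, 8 and 18 that lack SNF5 peaks, BRG1 promoter peaks per gene stood at 0.445 of the rest of the same chromosomes and other BRG1 peaks per Mb at 0.138, a ratio of 0.311 (0.227 to 0.420 over resampled windows of 10 Mb), so that 64.8% of BRG1 peaks there lay at promoters against 33.0%. A preference of BRM or SNF5 for promoters stays open, as depth is unknown.

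Peaks of all 3 lists lay in exons within SCHLAP1. Reads from the introduced construct, if it holds exons only, may be a source: 2 of 5 distinct sites in the gene were exonic, with an exact probability of 0.0106 at the exon share of the lists (one-sided), but that excess is the pattern itself and neither site is in all 3 lists. Occupancy of the resident gene is not excluded either, though 0 of its 3 BRM and SNF5 peaks lay outside exons. These sources cannot be told apart with 5 sites and with inputs not analysed here.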
